A study of Homo sapiens with 3 samples.

How the data were processed

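Chromatin immunoprecipitation followed by sequencing (ChIP-seq) recovers the DNA fragments bound by a protein with an antibody and counts where they pile up on the genome. It was done in FaDu, an established cell line from a squamous carcinoma of the pharynx, grown without treatment. Per the labels, 1 library was made with an antibody against ΔNp63α, 1 with an antibody against ZNF148 and 1 from input DNA without antibody. The labels' protocols name 3 independent ChIP assays as the source of the DNA. Each antibody has 1 peak list, so any variation among those assays is not visible in the values. The input library entered as a sample without a peak list used here.

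The submitters' processing notes name FastQC 0.11.9, Bowtie2 2.3.4.3, SAMtools 1.7, MACS2 2.2.6 and MultiQC 1.12 and the genome build hg19, without their role, order or settings. The chromosome and contig names in the lists are those of hg19. Which library served as the control in peak calling, whether duplicate reads were removed and which read filters were applied is not given in the sources used here. The lists have no header line, and their columns were read in the standard narrowPeak order. The deposited fold enrichment (a ratio over local background at the summit), the deposited −log10 p and −log10 q values and the summit position are the authors' own values for each peak. The deposited score equalled the whole part of 10 times −log10 q in every peak and was not used. The lowest deposited −log10 q was 3.01 for p63 and 3.02 for ZNF148, so weaker sites are outside both lists. The number of reads behind each peak and the depth of the libraries are unknown, so no read-based interval or detection floor is given. The q values were used to rank peaks within their own list. Folds describe peaks and were also set side by side between the lists, where differences in depth and background between the libraries enter.

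Peaks on chromosomes 1 to 22 and X were analysed. Regions prone to mapping artifacts were not filtered out. Rows with the same start and end, which hold separate summits of 1 interval, were counted as 1 peak with its most significant summit. This left 21520 of 21922 p63 rows and 37883 of 39669 ZNF148 rows. Rows on other chromosomes or contigs numbered 214 for p63 and 207 for ZNF148. Positions are 1-based hg19 coordinates.

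A p63 peak was called shared when it overlapped a ZNF148 peak by at least 1 bp, and the overlap count was checked against bedtools 2.31.1. The overlap expected from chance position alone was estimated from 1000 random placements. Each ZNF148 peak was moved to a uniform position on its own chromosome with its length kept, between the first and the last peak of either list there. A second set of 1000 placements, added after the data were seen, shifted each ZNF148 peak by 50 to 500 kb to either side, which keeps the regional density of peaks. Shares carry 95% Wilson intervals, which cover counting error only and treat peaks as independent. With 1 library per antibody, nothing measures the variation between replicates and no p-value is given. Summits were called close when they lay within 25 bp, a limit chosen after the distances had been seen. For rank classes, each list was divided by q value into 10 classes of equal size. Windows of 1 Mb and stretches of peaks no more than 12.5 kb apart were used to describe regions. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

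The overlap functions were tested on simulated lists with the numbers and lengths of the 21520 p63 and the ZNF148 peaks. With no planted sites the fold over placement was 1.01. With 20% of p63 peaks given a ZNF148 summit within 20 bp, 20.1% were recovered as close. Every planted pair met the 25 bp limit by design, so this checks the code only. The simulated peaks were placed uniformly, without the regional density of the real lists.

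Before the data were examined, the peaks to be named were fixed as the 10 highest by q value in each list and the 10 shared pairs with the best worse rank of their 2 members. Windows, stretches and chromosomes were chosen for naming after their values were seen. Promoter shares, motif content, placement at matched distance to transcription starts and 15 gene lists had also been planned. They need an hg19 sequence or annotation. The gene table used for names belongs to another build, coordinates were not converted, and peaks are therefore given by position without gene names. Alternatives tried were stricter q and fold limits, every summit counted, merging of neighbouring peaks, other overlap criteria, lists of equal length and other placements.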

Results

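Binding sites of 2 proteins were mapped by ChIP-seq in untreated FaDu cells. ΔNp63α is the N-terminally truncated form of p63, a transcription factor of the p53 family that marks the basal layer of squamous epithelia. ZNF148 is a zinc finger protein that binds GC-rich DNA. The data comprised 3 samples, an input library and 1 library per antibody, and the comparisons rest on the peak lists of the latter. There are no replicate lists, so no value below has a replicate error. Read depth is unknown from the lists.

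The p63 list held 21520 peaks covering 5.23 Mb, with a median length of 236 bp. Their median fold enrichment was 13.2 (quartiles 8.40 and 24.5), and the highest was 98.1. The ZNF148 list was longer, with 37883 peaks covering 10.3 Mb at a median length of 248 bp. Its peaks had a median fold enrichment of 9.83 (quartiles 7.21 and 16.6) and reached 127.7. Of the p63 peaks, 65.1% had a fold of 10 or more, against 49.6% of the ZNF148 peaks. List lengths depend on the depth and background of each library, so they do not rank the number of sites bound by each protein.

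The most significant p63 peak lay on chromosome X at 77359269 to 77359881, with a fold enrichment of 98.1 and a −log10 q of 502. It was followed by a peak on chromosome 2 at 178034904 to 178035312 (fold 92.9) and one on chromosome 9 at 139001474 to 139001871 (fold 86.3). The next were on chromosome 22 at 43145444 to 43145856 (fold 84.7), chromosome 9 at 139518302 to 139518886 (fold 72.9) and chromosome 2 at 173061600 to 173062045 (fold 91.8). The remaining 4 of the 10 highest lay on chromosome 17 at 4757646 to 4758023 (fold 97.0), chromosome 10 at 79658276 to 79658697 (fold 93.1), chromosome 1 at 207414047 to 207414377 (fold 81.9) and chromosome 7 at 409052 to 409450 (fold 81.3). Of these 10 p63 peaks, 6 overlapped a ZNF148 peak. The peaks on chromosomes 2, 22 and 1 did not.

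The most significant ZNF148 peak lay on chromosome 11 at 65625017 to 65625728, with a fold enrichment of 100.2 and a −log10 q of 395. Neighbouring peaks on chromosome 14 followed, at 77474140 to 77474830 (fold 103.8) and 77494572 to 77495960 (fold 110). The peaks on chromosome 15 at 79164791 to 79165292 (fold 127.7) and chromosome 1 at 211432266 to 211432823 (fold 127.1) had the largest folds of the 10. Chromosome 3 held a pair, at 177077337 to 177078089 (fold 107.4) and 176914109 to 176915974 (fold 107.1). The last 3 were on chromosome 9 at 140210044 to 140210984 (fold 112.3), chromosome 8 at 135724855 to 135725443 (fold 84.3) and chromosome 11 at 70962898 to 70964052 (fold 48.9). Of these 10 ZNF148 peaks, 3 overlapped a p63 peak, namely both on chromosome 14 and the one on chromosome 1.

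The title of the series asks whether p63 and ZNF148 act together, and the overlap of their lists addresses whether they were found at the same sites. Of the p63 peaks, 4560 of 21520 overlapped a ZNF148 peak, or 21.2% (95% Wilson interval 20.6 to 21.7%). In the other direction, 4569 of 37883 ZNF148 peaks overlapped a p63 peak, or 12.1% (11.7 to 12.4%). That share depends on the length of the list: it was 18.8% among as many of the most significant ZNF148 peaks as there were p63 peaks. Random placement of the ZNF148 peaks on their chromosomes gave 155 ± 12.5 shared p63 peaks (mean and SD of 1000 placements), and no placement gave more than 199. The observed count was 29.4 times that mean. When ZNF148 peaks were instead shifted by 50 to 500 kb, so that dense regions stayed dense, the mean was 223 ± 15.2, the maximum 290 and the fold 20.4. Most sites of either protein were not in the other list, with 16960 p63 and 33314 ZNF148 peaks unshared. The fold was 65.0 when sharing was defined by summits within 100 bp. Neither kind of placement kept ZNF148 peaks in open chromatin or at their distance to transcription starts. Overlap from a preference of both proteins for such DNA is therefore contained in these folds, and its part is unknown. Whether both lists were called against the same input is not given in the sources used here, and values that a common input would lend to both were not modelled.

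Shared sites were stronger, on the median, in both lists. Shared p63 peaks had a median fold enrichment of 26.2 (quartiles 14.1 and 42.0), against 11.7 (7.95 and 19.8) for unshared p63 peaks. Shared ZNF148 peaks had a median fold of 23.8 (13.0 and 39.0), against 9.26 (6.88 and 14.4) for unshared ones. In p63 rank class 1 of 10, 56.9% of peaks were shared (54.8 to 59.0%), and the share fell through every class to 8.36% in class 10 (7.27 to 9.61%). For ZNF148 it fell from 46.0% (44.4 to 47.6%) to 2.40% (1.96 to 2.94%). Stronger p63 peaks were also longer, with medians of 331 bp in class 1 and 160 bp in class 10. Shifted ZNF148 peaks gave 1.28% and 0.907% in these classes, so the observed share was 44.5 times the shifted one in class 1 and 9.22 times in class 10.

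**Figure D1:**
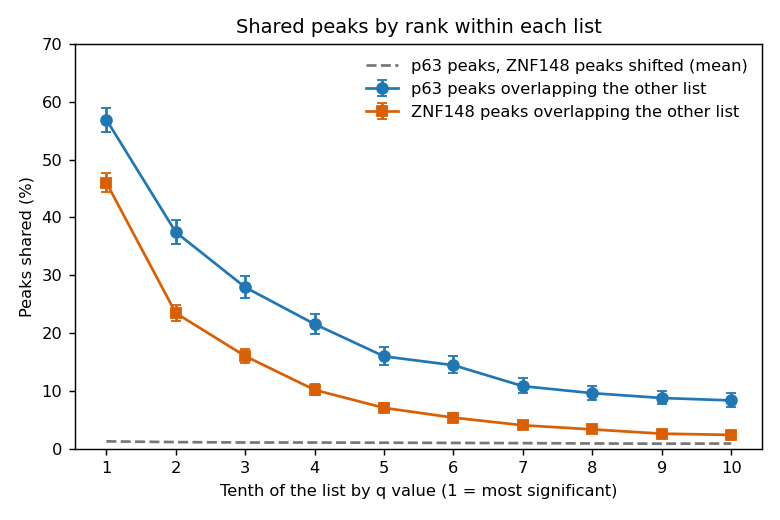
Percent of peaks overlapping a peak of the other list (y axis) in 10 classes of equal size ordered by q value within each list (x axis, 1 is the most significant). Points are p63 (circles) and ZNF148 (squares) with 95% Wilson intervals, and the dashed line is the mean for p63 when ZNF148 peaks are shifted; the share falls from 56.9% to 8.36% for p63 and from 46.0% to 2.40% for ZNF148.

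The summits of shared sites coincided closely. Of the 4560 shared p63 peaks, 2906 had a ZNF148 summit within 25 bp, or 63.7% (62.3 to 65.1%), and their median distance was 9 bp. No shift of the ZNF148 peaks gave more than 39 such sites, and the observed count was 132 times their mean. Only 9.86% of the overlaps formed by shifted peaks were this close. Across all p63 peaks, 1718 had a ZNF148 summit at 0 to 10 bp, against 9.10 ± 3.08 with shifted peaks, a ratio of 189. The ratio was 92.1 at 11 to 25 bp, 25.4 at 26 to 50 bp, 5.06 at 101 to 200 bp and 1.61 at 501 to 1000 bp. The close sites were strong in both lists, with a median fold of 31.8 for p63 and 31.0 for ZNF148. The other 1654 shared p63 peaks had a median fold of 16.8 and a median distance of 74 bp. Across the 2906 close sites the folds of both proteins rose together (Spearman's rho 0.75), and across the other 1654 the rho was 0.16. These correlations are across sites, which are not independent replicates.

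**Figure D2:**
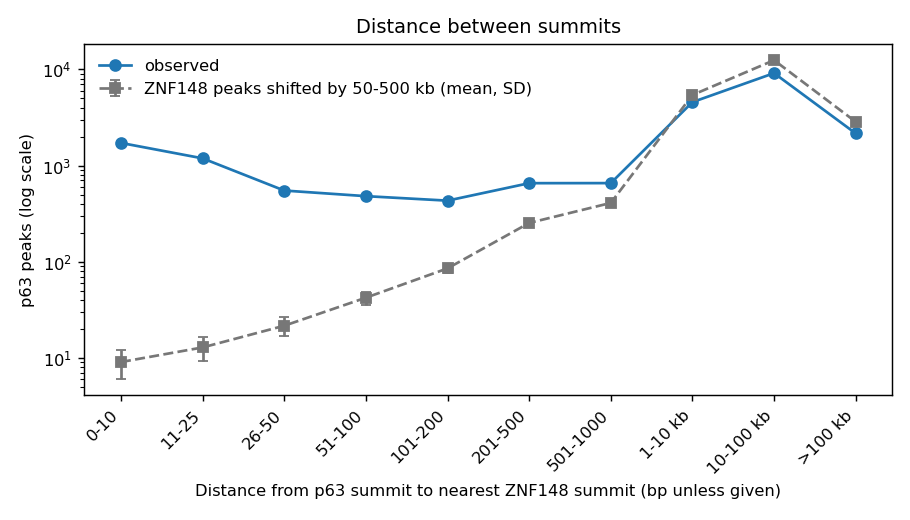
Number of p63 peaks (y axis, log scale) by the distance from their summit to the nearest ZNF148 summit (x axis, in bp up to 1000 and in kb beyond). Circles are the observed counts and squares the mean and SD over 1000 shifts of the ZNF148 peaks; 1718 observed summits lie at 0 to 10 bp, against 9.10 with shifts.

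The 10 shared pairs ranked highest in both lists had folds of 39.9 to 94.1 for p63 and 57.4 to 102.5 for ZNF148. The first was the p63 peak on chromosome 9 at 139001474 to 139001871, where the ZNF148 peak (139001459 to 139001978) had a fold of 102.5 and its summit lay 17 bp away. The second, on chromosome 9 at 139518302 to 139518886, had a ZNF148 fold of 76.4 and was the only one of the 10 with summits more than 25 bp apart, at 42 bp. Chromosome 8 held 3 of the pairs, at 102903882 to 102904349 with summits 4 bp apart, 129909164 to 129909502 with summits 1 bp apart and 115516315 to 115516861 with summits 5 bp apart. Chromosome 5 held 2, at 49452245 to 49452605 (2 bp) and 40541688 to 40542023 (16 bp). The other 3 were on chromosome 3 at 131050588 to 131050947 (4 bp), chromosome 11 at 69325287 to 69325670 (18 bp) and chromosome 1 at 61105949 to 61106309 (4 bp). Whether any of the 10 pairs lies in a region prone to mapping artifacts was not checked.

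Both proteins were distributed unevenly over the chromosomes. ZNF148 peaks were densest on chromosomes 22, 17 and 19, at 34.3, 30.7 and 29.5 per Mb, and sparsest on chromosomes 18, 4 and X, at 5.18, 6.34 and 6.50 per Mb. Chromosomes 17, 19 and 22 are known as gene-rich. p63 peaks varied less, from 4.40 per Mb on chromosome 18 to 13.6 per Mb on chromosome 22. Chromosome 19 had 1738 ZNF148 and 514 p63 peaks, a ratio of 3.38, while chromosome 18 had 404 and 343, a ratio of 1.18. The densities of the 2 proteins rose together across the 23 chromosomes (Pearson's r 0.90, Spearman's rho 0.93). Without chromosomes 18 and 22, the farthest from the median p63 density, r was 0.85. Chromosomes of 1 library are not replicates, so no p-value is given. Densities refer to the stretch between the first and the last peak of a chromosome.

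The share of p63 peaks found together with ZNF148 was highest on chromosomes X and 4, which had few ZNF148 peaks per Mb. On chromosome X, 37.9% of 712 p63 peaks were shared (34.4 to 41.5%) and 30.2% had close summits (26.9 to 33.7%). Chromosome 4 followed with 31.3% of 964 shared and 24.7% close (22.1 to 27.5%). Other sparse chromosomes were nearer to the overall 21.2%, with 21.9% shared on chromosome 18 and 19.1% on chromosome 13, while the denser chromosomes 5 and 11 had 26.1% and 23.7%. On chromosome 22, 14.9% of 477 were shared and 2.94% close (1.76 to 4.87%). Chromosomes 19 and 17 had 4.86% and 5.03% close. The intervals of chromosomes X and 22 do not overlap, but these have the highest and the lowest close share of the 23 chromosomes, so this is not a test. The ratio of their close shares, 10.3, depends on the limit: with summits within 50 bp the shares were 34.3% and 5.66% and the ratio 6.05. Across the 23 chromosomes, the close share fell with ZNF148 density (Pearson's r −0.77, Spearman's rho −0.82), and r was −0.72 without chromosomes 17 and 22. With the 50 bp limit r was −0.74 and rho −0.79. The share with any overlap fell less regularly (r −0.58, rho −0.69, and r −0.54 without the same chromosomes). Overlaps with summits farther apart rose with it, from 2.46% of p63 peaks on chromosome 13 to 11.9% on chromosome 22 (r 0.76, rho 0.68, and r 0.67 without the same chromosomes). All these relations across chromosomes were computed on the same 2 lists.

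**Figure D3:**
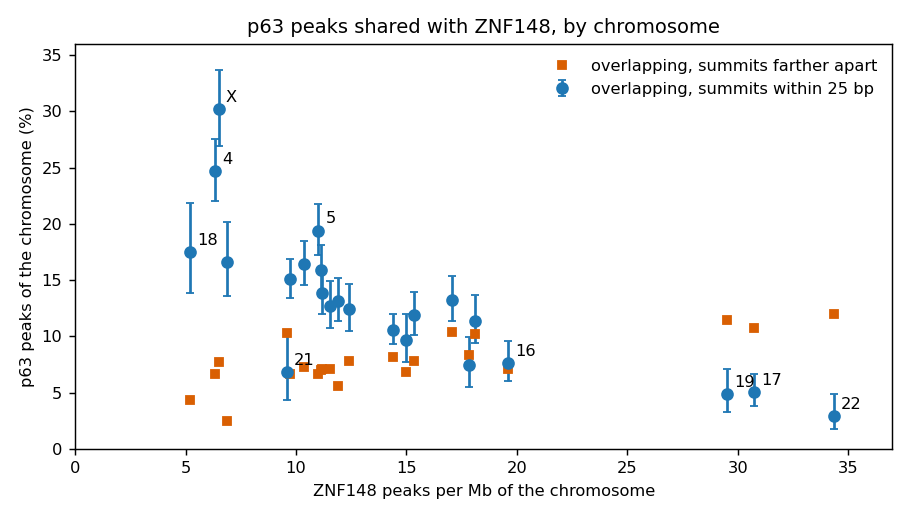
Percent of each chromosome's p63 peaks that overlap a ZNF148 peak (y axis) against the number of ZNF148 peaks per Mb (x axis), 1 point per chromosome. Circles with 95% Wilson intervals are overlaps with summits within 25 bp, which fall from 30.2% on X to 2.94% on 22, and squares are overlaps with summits farther apart, which reach 11.9% on 22.

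Several regions gathered peaks of one or both proteins. In windows of 1 Mb, p63 had a median of 6 peaks and ZNF148 of 9 over the 2865 windows with a peak. The window on chromosome 22 from 46 to 47 Mb held the most p63 peaks, 54, with 130 ZNF148 peaks and 15 shared p63 peaks. Chromosome 11 from 69 to 70 Mb held 33 p63 and 122 ZNF148 peaks, and from 65 to 66 Mb 31 and 123. ZNF148 was densest on chromosome 9 from 139 to 140 Mb, with 165 peaks against 23 for p63, and on chromosome 17 from 79 to 80 Mb, with 147 against 24. ZNF148 had more peaks in 65.3% of windows and p63 in 23.5%. The largest p63 excess was on chromosome 1 from 152 to 153 Mb, with 24 p63 and 8 ZNF148 peaks and none shared. Chromosome X from 61 to 62 Mb had 16 against 1, chromosome 19 from 43 to 44 Mb 20 against 6, chromosome 7 from 80 to 81 Mb 15 against 1, chromosome X from 58 to 59 Mb 11 against 0 and chromosome 2 from 192 to 193 Mb 18 against 8. In the windows on chromosome X, 15 of the 16 and all 11 p63 peaks belonged to 2 stretches of weak peaks with folds of 1.97 to 3.62 and 2.08 to 3.73, while 2.07% of all p63 peaks had a fold under 5. These windows were chosen after their values were seen. Copy number, which can change the reads and so the peaks called in a region, was not taken into account.

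A larger share of ZNF148 than of p63 peaks lay in stretches of neighbouring peaks. Stretches with 3 or more peaks no farther than 12.5 kb apart held 36.2% of ZNF148 peaks in 2824 stretches, and 9.37% of p63 peaks in 575. More peaks per Mb lengthen such stretches by themselves. Stretches were not compared between lists of equal length, so stronger clustering of ZNF148 is not established. The richest ZNF148 stretch, on chromosome 9 from 139393873 to 139524538, held 40 ZNF148 and 7 p63 peaks, and 5 of the ZNF148 peaks were shared. The next was on chromosome 22 from 46883281 to 47031753, with 36 ZNF148 and 15 p63 peaks. Within it lay a p63 stretch of 9 peaks, from 46910553 to 46959480. Other p63 stretches were on chromosome 14 from 77373161 to 77425940, with 9 peaks, and on chromosome 8 from 128864417 to 128879592, with 8 peaks of folds up to 47.6.

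**Figure D4:**
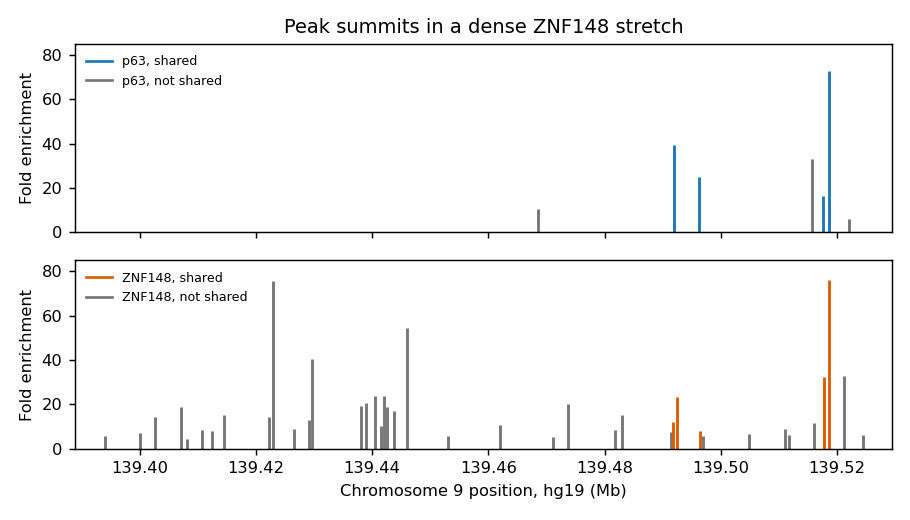
Fold enrichment (y axis) at each peak summit along the chromosome 9 stretch with the most ZNF148 peaks (x axis, hg19 position in Mb), with p63 above and ZNF148 below; coloured lines are shared peaks and grey lines unshared ones. The 40 ZNF148 peaks spread over the stretch from 139393873 to 139524538, while 7 p63 peaks lie at its right, including the shared p63 peak of fold 72.9.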

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

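All tests here were chosen after the result was seen, except the count of chromosomes by unshared ZNF148 peaks, whose prediction was set beforehand.

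Outside the analysed chromosomes lay 214 p63 and 207 ZNF148 rows, of which 118 and 139 were on contigs. More than 50% of the latter in each list were on 1 unplaced contig, gl000220, which is known to hold ribosomal DNA repeats. It carried 75 peak rows in the p63 list, in 31 intervals with a median fold of 2.36, and 75 in the ZNF148 list, in 40 intervals with a median fold of 3.62. Both counts of 75 are above 3, the limit that a count of 0 allows, which is why they are given; this shows that peaks were called there, not that their number is unusual. All other contigs together held 43 p63 and 64 ZNF148 rows, and 96 and 68 rows were on no contig.

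The first pattern weighed is the coincidence of summits within 25 bp at 2906 sites. Carry-over of p63 library reads into the ZNF148 library, if ample, would leave a ZNF148 peak at nearly every strong p63 site. Yet 44.7% of the 215 most significant p63 peaks (38.2 to 51.3%) had no ZNF148 summit within 1 kb. Ample carry-over the other way is argued against likewise. Of the 378 most significant ZNF148 peaks, 60.6% (55.6 to 65.4%) had no p63 summit within 1 kb. Read depth is unknown, so a smaller carry-over that adds to part of the close sites is not excluded. Chance values of a common input are not decided. The close share of overlaps was 6.46 times that of shifted peaks, but shifted peaks do not reproduce a background common to both lists, which might favour the same positions in each. Binding of both proteins at 1 site, an antibody that recovers the other protein's complexes and open chromatin enriched by both antibodies may each give this pattern, and they stay open too because no accessibility or control-antibody data were used here.

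The second pattern is the difference in close share between chromosomes, from 30.2% on X to 2.94% on 22. Stronger p63 peaks on some chromosomes are argued against as its cause, because with rank class held fixed the share on X was still 11.3 times that on 22, or 6.56 times with summits within 50 bp. Chance overlap with denser ZNF148 peaks would give a rise with density, and rho was −0.82; leaving out peaks beside long peak-free stretches left X at 31.1% (27.8 to 34.7%). The difference also ran within chromosomes. p63 peaks in windows of 1 Mb with fewer unshared ZNF148 peaks had the higher close share on 23 of 23 chromosomes, but that count leaves out the peaks that joined p63, so sharing itself lowers it and the test decides nothing. With every ZNF148 peak counted, joined ones included, the number was again 23 of 23 (on X by 31.5% against 28.4%, the smallest difference). It was also 23 of 23 when only the ZNF148 peaks of the 2 adjacent windows were counted, which sharing inside the window cannot change. A regional part is thus present, and a part that belongs to whole chromosomes was not separated from it. Base composition, gene density, p63 peak density and copy number could each vary this way and were not tested.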

How the results depend on the processing

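Of the 41 recomputed values, 25 stayed within the counting interval of the reported one (counts of peaks within 1.5 times), 16 moved outside it and 0 changed direction. Counts and shares of peaks have no direction to change, so the last number bears only on folds, ratios and correlations. The limit of 1.5 times is wide for counts of peaks, so staying within it says little. The number of peaks stayed within 1.5 times under every alternative run, from 21074 to 21708 for p63 and from 34594 to 39462 for ZNF148. The share of p63 peaks shared, 21.2%, became 17.99% when the overlap had to cover at least 50% of both peaks, 18.3% with summits within 100 bp and 18.8% with lists of equal length. The fold over placement, 29.4, became 65.0 with summits within 100 bp, 30.6 at q of 1e-05 or less, 20.4 with shifted ZNF148 peaks and 27.7 with peak-free stretches over 1 Mb left out; the last 2 were chosen after seeing the data, as were 25 of the 41 in all. The fold rose with summits within 100 bp because the observed share fell only from 21.2% to 18.3%, while the placed count fell by a larger factor. The close share on chromosome 22 became 5.66% when close meant 50 bp, against 34.3% on X. The 21 alternatives for promoters, motifs, matched distance to transcription starts and gene lists were not run, since no hg19 sequence or annotation was used here. No paired analysis was possible because each antibody has 1 library. Depth is unknown, so a site missing from a list may lie under its limit of about 3 in −log10 q, and unshared does not mean unbound. With the ZNF148 list cut to its 21520 most significant peaks, the share of p63 peaks shared fell from 21.2% to 18.8%.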

Other observations

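All values here were chosen after the data were seen. p63 peaks in regions with few ZNF148 peaks were those most often joined by ZNF148. Counts of the 2 proteins rose together across windows of 1 Mb (Spearman's rho 0.74). The density of p63 peaks was not held fixed, so the 2 densities are not told apart. In windows of 1 Mb with 0 to 7 ZNF148 peaks, joined ones counted, 23.7% of 5266 p63 peaks had a ZNF148 summit within 25 bp (22.5 to 24.8%). The share was 17.03% with 8 to 13, 9.16% with 14 to 26 and 4.01% (3.52 to 4.57%) with 27 to 165. With p63 rank class held fixed the first and last values were 23.7% and 3.99%. By the ZNF148 peaks of the 2 adjacent windows alone, the share fell from 22.5% with 0 to 14 to 4.57% with 46 to 239. Overlaps with summits farther apart were more frequent in dense windows, at 12.7% with 27 to 165 peaks and 4.84% with 0 to 7, but a denser list also meets more p63 peaks by chance. On chromosome X, 77.9% of the 154 p63 peaks in the most significant quartile of the list were shared, against 23.6% of 123 on chromosome 22. A candidate explanation is that the ZNF148 list holds 2 kinds of sites, one dense in certain regions with few p63 peaks at its summits and one at strong p63 sites elsewhere; the higher share beside sparse windows on 23 of 23 chromosomes (ZNF148 peak density of adjacent windows) is another view of the density pattern that prompted this idea, so it does not test it. Motif content or accessibility at both sets of sites would, and neither was used here.

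p63 peaks that overlapped no ZNF148 peak had ZNF148 summits in their neighbourhood slightly more often than with shifted peaks. Of 16960 such peaks, 33.5% (32.8 to 34.2%) had one within 10 kb, against 30.2% with shifts of 50 to 500 kb and 24.2% with uniform placement. Over all p63 peaks, shared ones included, the ratio to shifts was 1.61 at 501 to 1000 bp and 0.843 at 1001 to 10000 bp. Each peak counts only at its nearest summit, so shared peaks lower the latter ratio, and it does not show depletion. How much of the excess within 10 kb lay under 1 kb was not separated.

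The p63 stretches with the most peaks lay on chromosome X. They held 15 peaks from 61682230 to 61719896 and 11 from 58566475 to 58581667, with folds of 1.97 to 3.73 and no ZNF148 peak in either. The p63 list has a median fold of 13.2, so these peaks are weak. Whether they reflect binding or a mapping artifact was not tested, and regions prone to such artifacts were not filtered out. On the same chromosome, 114971675 to 115005227 held 8 p63 peaks of folds 4.86 to 7.28 and 18 ZNF148 peaks.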
